A study of Drosophila melanogaster with 8 samples.

How the data were processed

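RNA was measured in ventral nerve cords of female wandering Drosophila melanogaster larvae of 2 genotypes in a w1118 background, with 4 libraries each. Mutants carried witA12 over witB11, both on chromosomes marked with st1, and controls carried the witA12, st1 chromosome over a wild-type one. Per the labels' protocols, larvae grew at 25 °C with 80 per vial, each biological replicate pooled 25 nerve cords, and stranded mRNA libraries were read as 42 bp pairs. The gene wit (wishful thinking) encodes a type II receptor for BMP ligands.

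The deposited values are estimated counts per gene, and kallisto 0.43.0, DESeq2 and genome build BDGP6 are named per the submitters' processing notes, without a stated role for DESeq2. How transcript estimates were summed to genes, and any filter before that, is not given in the sources used here. Of the estimated counts 31.36% were not whole, and all were rounded before testing. Each file held the same 14175 gene identifiers, of which 13948 were named from a table of gene identifiers and 1 through an older identifier, and 226 kept their identifier. Chromosome, start and end came from Ensembl release 115 for the same assembly. A gene listed for analysis whose symbol matched no identifier was not analysed here, which holds for 37 of the 713 list entries. Transcript estimates share reads between near-identical copies, so values of such genes are uncertain, and 120 genes with a total of 80 or more had counts identical to those of another gene in all 8 libraries.

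Totals ran from 20923717 to 32740480 estimated counts per library, so 3 counts corresponded to between 0.0926 and 0.142 CPM. Intervals and floors on counts cover counting error only. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10), libraries were scaled by TMM, and genotype was tested with edgeR's quasi-likelihood test with robust estimation and no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. Values are CPM on TMM-scaled totals with SD over 4 libraries, and log2 fold changes are mutant over control with the standard error from the quasi-likelihood F statistic. R 4.3.3, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0 were also used, and figures were drawn with matplotlib 3.10.9.

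The design, the 32 gene lists, the rule for named genes and the list of alternatives were fixed before the data were examined. Lists with 3 or more measured genes were tested with limma's camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. Named genes were wit and st, every measured gene of the 2 BMP lists, and up to 4 genes with the smallest adjusted p from each other list. They also included the 12 largest rises and 12 largest falls among called genes with a mean of 1 CPM or more in the higher group and no overlap between genotypes. Genes named outside that rule were chosen after their values were seen, and are said to be so where they appear. The share of changed genes on chromosome 3 was tested with a two-sided Fisher's exact test, because the genotypes differ in 1 copy of chromosome 3 as a whole.

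On data simulated from the means and library sizes of these 8 libraries for 9114 genes, with 200 genes changed, the test called 62% of genes changed 1.25-fold, 81.6% of those changed 1.5-fold, 91.8% of those changed 2-fold and 100% of those changed 4-fold. It made 172 calls, 6 of them on genes that had not been changed, and 0 calls when no gene was changed. Each gene was drawn independently with its own dispersion, without swings shared between libraries, so these rates may not hold for the real data. Pairs of libraries of one genotype differed by more than sampling noise, with chi-square per degree of freedom from 3.80 to 36.0, so no library was counted as a duplicate. Alternatives were DESeq2's size factors, DESeq2's Wald test, limma-voom with sample quality weights, 2 other count filters, a replicate block, 1 surrogate variable, and leaving out each library. Tests for sequence elements bound by BMP effectors were not run.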

Results

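Ventral nerve cords of wit mutant larvae were compared with those of control larvae that carried a single mutant wit allele, with 4 libraries of 25 nerve cords for each genotype. The comparison asks which genes of the nerve cord depend on the BMP type II receptor encoded by wit. Control libraries 1 to 4 held 28719803, 26746219, 27888673 and 32740480 estimated counts, and mutant libraries 1 to 4 held 20923717, 25410835, 32028719 and 28327683. Log2 CPM values correlated at 0.989 to 0.996 within genotypes and at 0.983 to 0.988 between them. The first principal component held 48.2% of the variance and separated all control from all mutant libraries, while mutant replicate 1 lay farthest from the other mutants on the second, which held 14.3%.

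The wit transcript itself (FBgn0024179, chromosome 3L, 4064152 to 4071717) was at 90.6 ± 3.43 CPM in controls and 86.8 ± 3.97 CPM in mutants (SD, n = 4 each). Its log2 fold change was -0.06 (SE 0.04, edgeR adjusted p = 0.371), and as the labels do not give the lesions, transcript abundance does not check the genotype. The eye-colour transporter gene st, whose st1 marker is on 1 chromosome in controls and on both in mutants, fell from 0.410 ± 0.034 to 0.187 ± 0.035 CPM (adjusted p = 0.0297). That call held in 3 of 12 alternatives that tested it and was lost, among others, without control replicate 2 or 3 or mutant replicate 2, 3 or 4 (adjusted p 0.0537 to 0.0718).

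Of 9176 genes tested, 562 were higher and 795 lower in mutants, which is 14.8% of the genes. Changes of 2-fold or more were found for 168 genes, 61 higher and 107 lower. The 4 mutant and 4 control values did not overlap for 1882 genes, 20.5% of those tested against 2.86% by chance, and 1241 of these were among the changed genes. The count of genes higher in wit mutants depended on single libraries: it was 1060 without mutant replicate 1, 361 without mutant replicate 2 and 350 without mutant replicate 3. Without control replicates 2, 3 and 4 it was 304, 311 and 359, and the count of genes lower in wit mutants was 524 without control replicate 2.

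Of 7 measured genes reported as BMP targets in neurons, 3 fell and 0 rose. The Twit gene (twit) fell 10.2-fold, from 56.7 ± 3.20 to 5.57 ± 1.73 CPM (log2 fold change -3.35, SE 0.17, adjusted p = 1.05e-05). The neuropeptide gene FMRFa, expressed in neurosecretory neurons under BMP control, fell 5.29-fold, from 70.7 ± 3.31 to 13.5 ± 1.61 CPM (log2 fold change -2.40, SE 0.07, adjusted p = 6.81e-09). Dad, which encodes an inhibitory Smad induced by BMP signalling, fell 1.46-fold, from 64.6 ± 3.83 to 44.4 ± 1.98 CPM (adjusted p = 2.62e-05). The other 4 measured targets did not pass the test, with log2 fold changes of -0.07 for brk, -0.05 for Fmr1, -0.04 for trio and -0.01 for Khc-73. The list passed the camera test (adjusted p = 0.000926) but not with an estimated correlation (adjusted p = 0.251), and 3 genes were called when adjusted over the list alone. With fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, its adjusted p was 2.29e-05. The list was fixed without the reported direction of each target, so these tests do not show whether the targets moved as reported.

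**Figure D1:**
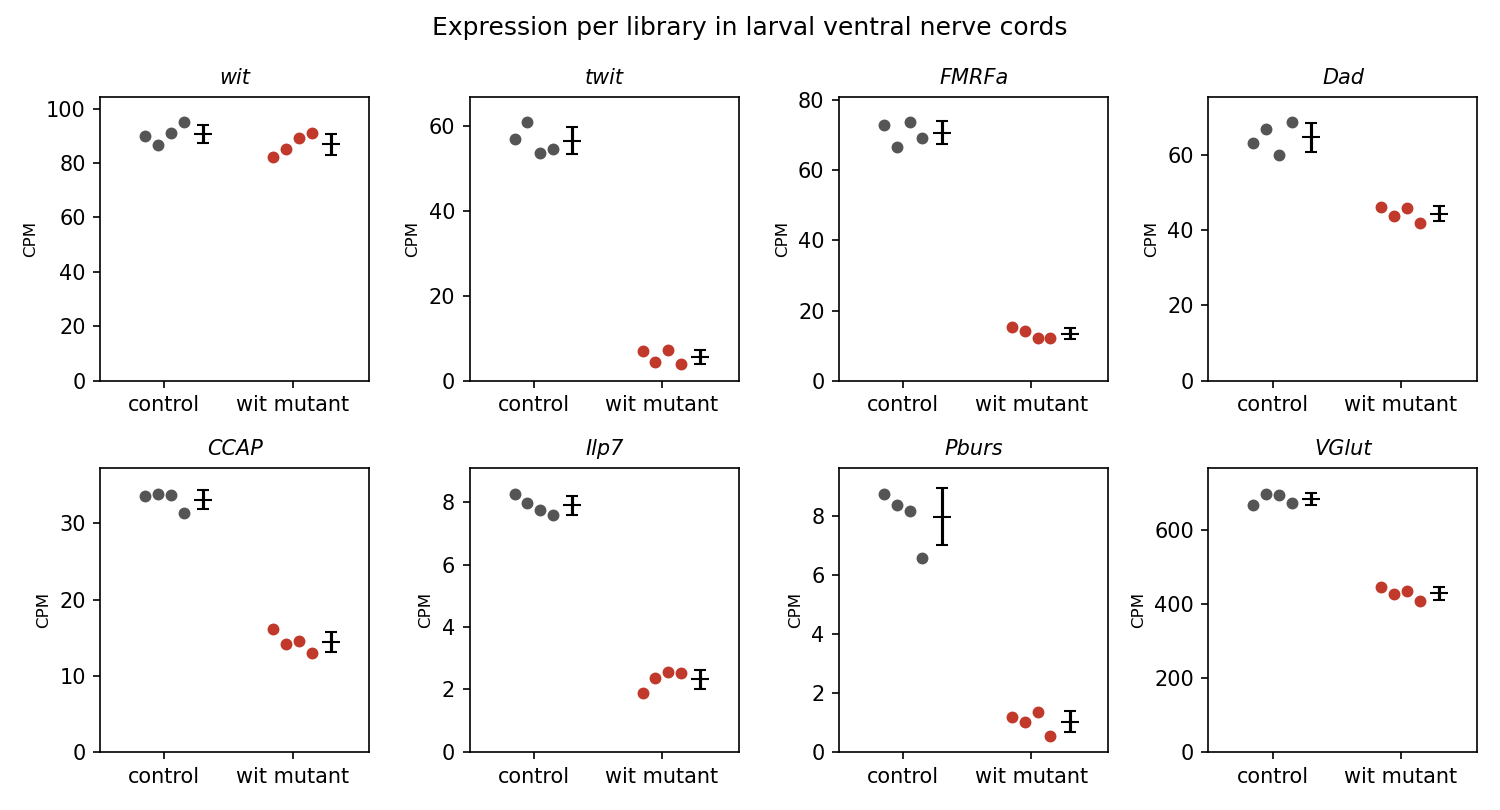
CPM (y axis, from 0) of 8 genes in each of the 4 control (grey) and 4 mutant (red) libraries, with the mean and SD beside the points. Control and mutant points overlap for wit and are separate for the other genes; twit averaged 56.7 CPM in controls and 5.57 CPM in mutants.

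Among 28 measured BMP pathway components, 8 fell and 2 rose. The activin-type ligand gene Actbeta fell from 214 to 150 CPM (log2 fold change -0.51, SE 0.03), and the BMP-binding protein gene cv-2 fell from 71.6 to 45.5 CPM (-0.65, SE 0.05). The furin gene Fur1 (-0.53), the ligand genes daw (-0.56) and dpp (-0.42), Dad, the Smad cofactor gene shn (-0.20) and nwk (-0.18) also fell, while cmpy (0.15) and the protease gene tld (0.29) rose. Of the 18 that did not pass the test, the ligand gene gbb had a log2 fold change of 0.17 (adjusted p = 0.0859), the type I receptor genes tkv and sax had -0.06 and 0.04, the type II receptor gene put had -0.02, and the transducer genes Mad and Smox had -0.10 and -0.02. Leaving out control replicate 2 or 3 ended the calls of shn, nwk, cmpy and tld, as did leaving out control replicate 4 (shn, nwk, tld) and mutant replicates 2 (shn, nwk), 3 (shn, cmpy, tld) and 4 (shn, nwk, tld). Adjusted p then ran to 0.0811 for shn, 0.0987 for nwk, 0.0631 for cmpy and 0.142 for tld, and Mad passed with 1 surrogate variable. The list passed camera (adjusted p = 0.0124) but not with an estimated correlation (adjusted p = 0.456), and 12 genes were called when adjusted over the list alone.

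Of 35 measured neuropeptide and hormone genes, 14 fell and 3 rose. CCAP, which encodes crustacean cardioactive peptide, fell 2.30-fold from 33.1 ± 1.21 to 14.4 ± 1.33 CPM (adjusted p = 2.27e-07). The insulin-like peptide gene Ilp7 fell 3.35-fold from 7.90 ± 0.298 to 2.33 ± 0.304 CPM (adjusted p = 1.11e-06). Pburs, a subunit gene of the hormone bursicon, fell 7.75-fold from 7.98 ± 0.967 to 1.03 ± 0.350 CPM (adjusted p = 5.49e-06). The 3 genes that rose, named after their values were seen, were Nplp1 (0.35), Ptth (1.04) and CCHa1 (0.49), where the calls of Ptth and CCHa1 were lost with the replicate block (adjusted p = 0.0641 and 0.0701), and that of CCHa1 also without control replicate 1, 2 or 4 or mutant replicate 2 (0.0601 to 0.0696). The list passed camera (adjusted p = 9.91e-06) but not with an estimated correlation (adjusted p = 0.456), and 18 genes were called when adjusted over the list alone. Of 10 measured genes for peptide processing and release only Fur1 passed; the peptidergic factor gene dimm had -0.40 (adjusted p = 0.0754) and IA-2 had -0.20 (adjusted p = 0.0576; 0.00408 without mutant replicate 1). That list did not pass camera (adjusted p = 0.454), and 6 genes were called when adjusted over the list alone.

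Of 16 measured genes of transmitter synthesis and transport, 6 fell, 1 rose and 9 did not pass the test. The vesicular glutamate transporter gene VGlut, expressed in fly motor neurons, fell 1.59-fold from 684 ± 15.8 to 429 ± 16.9 CPM (log2 fold change -0.67, SE 0.04, adjusted p = 6.99e-07). The vesicular monoamine transporter gene Vmat fell from 635 to 446 CPM and the serotonin synthesis gene Trhn from 22.9 to 14.9 CPM, while the dopa decarboxylase gene Ddc rose from 42.3 to 58.9 CPM. The acetylcholine synthesis gene ChAT, named after its value was seen, had -0.31 (adjusted p = 0.0958; 0.0154 without mutant replicate 1). Of 15 motor neuron transcription factor genes only zfh1 fell (-0.22, adjusted p = 0.0081), and vvl and exex had -0.10 and -0.18 without passing. That list did not pass camera (adjusted p = 0.255), with 1 gene called when adjusted over the list alone. The transmitter list passed camera (adjusted p = 0.000361) but not with an estimated correlation (adjusted p = 0.456), and 9 genes were called when adjusted over the list alone.

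Synapse and axon guidance genes that changed were lower. Of 32 active zone and vesicle genes 15 fell and 0 rose, including Syx1A (-0.34), Rbp (-0.48), Rab3 (-0.30) and EndoA (-0.25), with a list median of -0.13. Of 43 axon guidance and adhesion genes 18 fell and 0 rose: the adhesion genes Fas2 and Nrg went from 579 to 377 CPM and from 619 to 486 CPM, and beat-Ia and beat-Ic had -0.62 and -0.27. Of 23 ion channel genes 4 fell, namely Slob (-0.72), eag (-0.37), tipE (-0.16) and Ca-alpha1T (-0.23), where eag lost its call with the replicate block (adjusted p = 0.0514), and Ca-alpha1T also without control replicate 2, 3 or 4 or mutant replicate 2 or 4 (0.0651 to 0.119). These lists passed camera with adjusted p of 1.09e-06, 4.01e-08 and 0.00513, and missed it with an estimated correlation at adjusted p of 0.456, 0.456 and 0.551. Adjusted over the list alone, 22, 21 and 4 genes were called. In all, 9 lists passed camera at the preset correlation and 0 with an estimated one. Of the 35 splits of the 8 libraries 9, the real one included, gave as many, so the splits do not separate the number of lists from chance. Some other splits keep most libraries of a genotype together, so part of the genotype difference stays in them. Splits with 2 control and 2 mutant libraries on each side do not, and they still gave from 1 to 9 lists. With fry, adjusted p was 0.0142 for active zone, 0.00582 for axon guidance, neuropeptide, transmitter and glia genes, 0.00495 for BMP components, 0.0587 for ion channels and 0.300 for glycolysis. Of the lists that did not pass camera, hemocytes and imaginal discs (0.00582) and motor neuron transcription factors and oxidative stress (0.0313) passed fry.

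**Figure D2:**
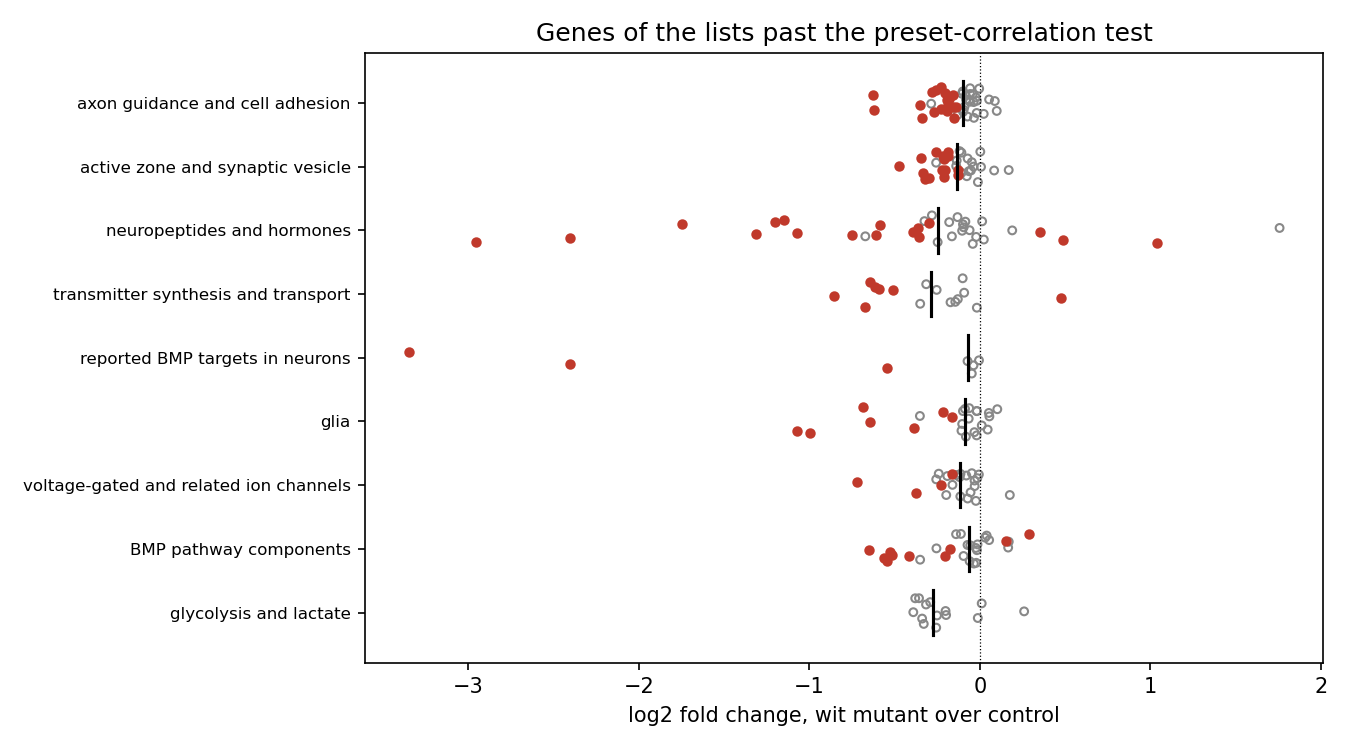
Log2 fold change, mutant over control (x axis), of each measured gene in the 9 lists past the preset-correlation test (rows); filled red points are genes past the edgeR test, open points are not, and the black bar is the list median. Medians lie between -0.28 and -0.07, and none of these lists passes with an estimated correlation.

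Genes of neuromuscular junction growth and transmitter receptor genes changed in both directions. Of 31 genes of neuromuscular junction growth and cytoskeleton 6 fell, among them Fas2, Ank2 (-0.40) and Nlg3 (-0.18), and 2 rose, the profilin gene chic (0.30) and dia (0.18), the latter named after its value was seen and lost without control replicate 3 or 4 or mutant replicate 2 or 3 (adjusted p 0.0503 to 0.0695). Of 37 transmitter receptor genes 7 fell, including 5-HT1A (-0.24) and Octbeta1R (-0.34), and 2 rose: the dopamine receptor gene Dop1R1 went 1.78-fold up from 96.7 ± 8.39 to 172 ± 14.4 CPM (adjusted p = 4.52e-05), and GABA-B-R3 had 0.17. Of 20 axonal transport motor genes only BicD fell (-0.18). The 3 lists did not pass camera (adjusted p = 0.357, 0.0760 and 0.649), though transmitter receptors did without control replicate 1 (0.0141) or mutant replicate 3 (0.0314), and 9, 9 and 1 genes were called when adjusted over the list alone.

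Markers of other cells in the dissected tissue were also lower in part. Of 24 glial genes 7 fell and 0 rose. The midline glia gene wrapper went from 165 ± 4.37 to 127 ± 4.69 CPM (edgeR adjusted p = 3.62e-05). Nrx-IV (-0.16), Eaat1 (-0.21), vkg (-1.07), Col4a1 (-0.69), Gs2 (1.99-fold lower) and Gat (-0.65) also fell, the last 2 named after their values were seen. Gs2 ranged from 557 to 574 CPM over controls and from 183 to 418 CPM over mutants, with mutant replicate 1 highest. The calls of Col4a1, Gs2 and Gat were lost without any 1 of the 4 control replicates or mutant replicate 2, and those of Gs2 and Gat also without mutant replicate 3 (adjusted p 0.0564 to 0.0865, 0.0669 to 0.0893 and 0.0651 to 0.100). Eaat1 lost its call without control replicate 2 or 3 or mutant replicate 2 or 4 (0.0508 to 0.0768). The collagen IV genes vkg and Col4a1 also belong to the hemocyte list, of which 3 of 10 fell, the other being PPO2 (-1.10), whose call was lost without any 1 library other than control replicate 2 (adjusted p 0.0505 to 0.101). The glia list passed camera (adjusted p = 0.00459) but not with an estimated correlation (adjusted p = 0.451), with 7 genes called when adjusted over the list alone, and hemocytes did not pass (adjusted p = 0.122; 4 genes over the list alone).

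Remaining marker lists did not pass camera. For imaginal discs (15 measured) vn, a ligand gene of the EGF receptor, fell from 19.5 to 8.55 CPM, ptc, dpp and sd also fell, sd being named after its value was seen, and vg rose (camera adjusted p = 0.122; 5 genes when adjusted over the list alone). For optic lobe and central brain (15 measured) bi (-0.28) and so (-1.07) fell (0.427; 2 genes). For muscle (18 measured) Strn-Mlck rose (0.33) and bt fell (-0.61; list 0.739, 2 genes). For fat body (15 measured) GNBP1 (0.71) and bmm (0.25) rose while apolpp (-0.34) and Col4a1 fell (0.739, 4 genes), with a positive list median and mean and a downward camera direction. For trachea (7 measured) Gasp rose (0.59; list 0.133, 2 genes), and the list passed without mutant replicate 1 (0.0317). For male dosage compensation and germline (4 measured) msl-2 rose (0.15; list 0.842, 1 gene). No gene passed for ring gland (3 measured, 0.660) or cuticle (6 measured, 0.943), with 0 over each list alone. Leaving out control replicate 2 or 3 or mutant replicate 2 ended the calls of sd, vg, so, bmm, Gasp and msl-2. Control replicate 1 did so for vg, so, bmm and msl-2, control replicate 4 for sd, vg, bmm and Gasp, mutant replicate 3 for all but msl-2, and mutant replicate 4 for sd, bmm, Gasp and msl-2. Adjusted p then ran to 0.133 for sd, 0.138 for vg, 0.0686 for so, 0.118 for bmm and Gasp and 0.105 for msl-2.

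Of 34 neuroblast and cell division genes stg (-0.21), numb (-0.17) and grh (-0.16) fell (camera adjusted p = 0.142, and 0.00194 without mutant replicate 1 and 0.00658 with limma-voom; 2 genes when adjusted over the list alone). Of 20 temporal and ecdysone genes EcR (-0.16) and ab (-0.20) fell (0.842; 2 genes), with a positive list median and mean and a downward camera direction. Of 8 Hox genes 0 passed, also over the list alone, with -0.06 for Antp and 0.03 for Ubx (0.588). Of 21 heat shock genes Hsp70Ba (1.52), Hsp70Bb (0.61), crc (0.24), DnaJ-1 (0.15) and CG4456 (1.23) rose and Hsp68 (-0.43) and Hsp83 (-0.21) fell (0.122, and 0.0389 without control replicate 1 and 0.0421 with limma-voom; 8 genes), where the Hsp70 genes are near-identical copies and so uncertain, and DnaJ-1, CG4456 and Hsp83 were named after their values were seen. Of 15 oxidative stress genes GstE3 rose (1.12) and Gclc (-0.35) and GstE1 (-0.42) fell (0.122, and 0.0400 without mutant replicate 1; 5 genes). Of 6 immune genes the cecropin gene CecC fell (-3.47; 0.299; 1 gene), of 15 injury genes Diap1 rose (0.15; 0.588; 0 genes) and of 14 insulin genes foxo fell (-0.39) and bmm rose (0.660; 4 genes). Glycolysis passed camera (adjusted p = 0.0191; 0.765 with an estimated correlation) with 0 of 14 genes past edgeR's test or when adjusted over the list alone; Gapdh1 and Pfk had -0.39 and -0.36 (adjusted p = 0.0751 and 0.118), and passed without mutant replicate 1 (0.00708 and 0.0344). The glycolysis list missed camera without mutant replicate 2 (0.0793) or 4 (0.155) and with the DESeq2 Wald test (0.0766). Of 13 mitochondrial transcripts 0 passed, also over the list alone (0.588). Leaving out control replicate 3 ended the calls of stg, numb, grh, EcR, ab, Hsp70Bb, DnaJ-1, CG4456, Hsp83, Gclc, Diap1 and bmm. Control replicate 2 did so for stg, numb, grh, EcR, ab, CG4456, Hsp83, Gclc, GstE1, Diap1 and bmm. Control replicate 4 did so for grh, ab, DnaJ-1, Hsp83, Gclc, GstE1, Diap1 and bmm, and control replicate 1 for grh, CG4456, GstE1 and bmm. Mutant replicate 2 did so for numb, grh, EcR, ab, CG4456, Hsp83, GstE1, Diap1 and bmm, mutant replicate 3 for these and for stg and DnaJ-1, and mutant replicate 4 for ab, CG4456, Hsp83, Gclc, GstE1, Diap1 and bmm. The highest adjusted p among these was 0.127, for grh.

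Apart from twit, the 12 largest falls and 12 largest rises under the naming rule were in genes outside these lists. That rule left out CecC of the immune list, with a log2 fold change of -3.47. The gene thw (chromosome 3R, 7224414 to 7241138) fell 106-fold from 26.9 ± 2.46 to 0.256 ± 0.094 CPM (adjusted p = 2.10e-10), and p24-2 fell from 7.56 ± 1.04 to 0.034 ± 0.068 CPM. The pseudogenes CR43216, CR43213 and CR43211, with identical counts in all libraries, went from 2.57 ± 0.413 CPM to 0 counts, which is at least 22.6-fold lower against 3 counts per library. The neighbouring pseudogenes CR43214 and CR43215, named after their values were seen, rose from 4.20 to 8.61 CPM, so reads of this family are not assigned with certainty, and those calls were lost without control replicate 2 (adjusted p = 0.0548) and with the replicate block (0.0563). CG12607 and CG13032 were left with 1 mutant count each, for count ratios of 174 (95% counting interval 30.9 to 6919) and 113 (19.8 to 4488). The histone copy His1:CG33816, CG31220, SkpB, twit and lovit completed the 12 largest falls, at log2 fold changes of -4.96, -4.68, -3.59, -3.35 and -3.33. SmydA-6 and CG31380 held 2 and 3 control counts against 135 and 121 mutant counts, for count ratios of 71.3 (19.4 to 595) and 42.6 (14.2 to 209). Ada1-1 (4.45), CR43276 (4.29), CG41284 (3.31), CG18853 (2.32), CG3505 (2.07), CG13056 (2.03), the peroxiredoxin genes Prx6c (1.68) and Prx6b (1.58), osy (1.57) and CG30059 (1.56) completed the 12 largest rises.

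Changed genes lay on each of the 6 chromosome arms tested, and chromosome 3, of which 1 copy differs between genotypes, did not hold a share past the test. Chromosome 3 held 602 of the 1326 changed genes with a mapped arm (45.4%) and 43.8% of the genes that did not change (odds ratio 1.07, 95% interval 0.948 to 1.20, Fisher's exact p = 0.281). Its share was 48.1% of the higher genes (Fisher's exact p = 0.0510) and 43.5% of the lower genes (Fisher's exact p = 0.879). Of 329 genes tested within 1 Mb of wit or st, 57 changed. By arm, the share of tested genes that changed ran from 12.9% on X to 19.0% on chromosome 4, and no arm passed after Benjamini-Hochberg adjustment over 6 arms (lowest adjusted p = 0.118, for X). For the chromosome 3 share of changed genes, the odds ratio was 1.18 without control replicate 2 (Fisher's exact p = 0.0263) and 1.23 without control replicate 4 (Fisher's exact p = 0.00294), so an excess of chromosome 3 genes is not excluded.

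**Figure D3:**
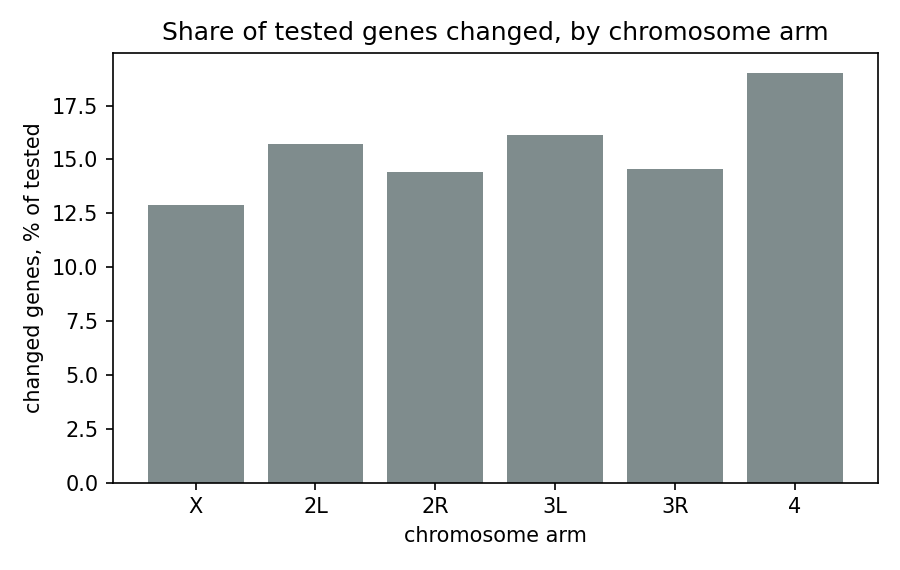
Share of tested genes that changed (y axis, percent, from 0) for each chromosome arm (x axis). Bars run from 12.9% for X to 19.0% for chromosome 4, where 79 genes were tested.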

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

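The tests of reads per library and of gene length were fixed before their results were seen, as were the counts of splits, and the other tests here were chosen after. Groups of 4 values were screened for a library far from the others: 21 of 302 groups exceeded Dixon's 95% critical value for 4 libraries, where chance gives about 1 in 20, or 15.1.

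Among controls, replicate 1 stood apart for cv-2 (gap over range 0.860, 75.1 CPM against at most 70.8), chic (0.926, 1567 CPM against at most 1366), His1:CG33816 (0.892, 0.497 CPM against at least 1.84), SmydA-6 (1, the only control with counts) and CG31380 (0.833, 0 CPM). Replicate 2 stood apart for Prx6c (0.846), EndoA (0.891) and Eaat1 (0.891, 202 CPM against at most 187), replicate 3 for Ada1-1 (0.833), CCHa1 (0.861) and GstE1 (0.858), and replicate 4 for CCAP (0.883, 31.3 CPM against at least 33.6). Among mutants, replicate 1 stood apart for brk (0.891, 31.8 CPM against at least 37.5) and CG12607 (1, the only one with a count), and replicate 2 for CG13032 (1, likewise). Replicate 3 stood apart for CG18853 (0.854), sd (0.864) and the pair CR43214 and CR43215 with identical counts (0.945), and replicate 4 for p24-2 (1, the only one with counts) and BicD (0.847).

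Of 35 neuropeptide genes 14 fell in wit mutants, 3 rose and 18 did not pass the test. A lower share of neurons would move them all by about the median of active zone genes (-0.13), but 60% of them, 21 of 35, lay more than 2 standard errors from it, 15 below and 6 above. Fewer reads in the mutant libraries would end the calls when all libraries are thinned to the smallest total, 20923717, but 92.9% of the lower peptide genes, 13 of 14, were still lower. Both argue against these as the whole cause. Loss of the cells that make these peptides was not tested, so lower transcription in living cells and fewer cells stay open, next to the genotype itself.

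Of the active zone genes 15 of 32 fell and of the axon guidance genes 18 of 43, and 0 rose. A lower share of neurons would raise markers of the cells that take their place. The glia list had a median of -0.085 (bootstrap interval over genes, taken as independent, -0.16 to -0.02), which argues against a shift from neurons to glia. Lists of other cells had medians above 0 for trachea (0.18), fat body (0.14) and ring gland (0.11). Medians were below 0 for hemocytes (-0.39), cuticle (-0.09), muscle (-0.08) and imaginal discs (-0.06). A larger share of other cells is therefore not excluded. Swings shared between libraries are argued against as the source of the falls themselves: fry, which allows for correlation between genes, gave p of 0.00126 for axon guidance and 0.00399 for active zone genes, and mean log2 CPM did not overlap (7.83 to 7.91 in controls and 7.66 to 7.75 in mutants; 8.41 to 8.48 and 8.23 to 8.36). For a larger fall than in other genes such swings cannot be told apart from an effect of genotype, because camera with an estimated correlation gave the axon guidance list an unadjusted p of 0.0866. Gene length may account for part: these genes are long (median 6273 exonic bases against 2236 for all tested genes), and 58.5% of the median log2 fold change of both lists was left once the trend of fold change on length was removed. Of the 35 splits of the 8 libraries, 9 gave as many lists past the camera test as the 9 of the real one, and the highest other gave 12. Some splits keep most libraries of a genotype together, so part of the genotype difference stays in them. Splits with 2 control and 2 mutant libraries on each side do not, and they still gave from 1 to 9 lists. Lists can thus pass at the preset correlation without a genotype difference between the sides, and chance is not excluded for the number of lists.

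Genes changed between genotypes, and by their stated genotypes the mutants differ from controls in 1 copy of chromosome 3. Whether they also differ on other chromosomes was not tested. If most changed genes were due to linked variants acting on genes of chromosome 3 itself, about 71.9% would lie there, against 45.4% found (exact interval 42.7 to 48.1%), which argues against these as the main cause, while linked variants that change genes on other chromosomes were not tested and stay open. For the 25 genes changed 8-fold or more, 60% lay there (38.7 to 78.9%), so such variants may lie behind many of these, and the 10 on other chromosomes are left without a tested explanation. That interval takes genes as independent, whereas CR43216, CR43213 and CR43211, which changed this much, held identical counts. In the real split 562 genes were higher, 795 lower and 168 changed 2-fold or more, and in the other splits at most 3, 3 and 1. Only 1 of 35 splits, the real one, gave as many in each case, the smallest share that 35 splits allow. That argues against chance, though each other split mixes the genotypes, so a genotype difference itself keeps its counts low. For chromosome 3 the splits decide nothing, since 31 of the 34 others had no changed gene to place: 1 split, the real one, had a p as small as 0.281, and the smallest other was 0.440.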

How the results depend on the processing

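Of the 1357 changed genes, 0 turned sign in the refits, leaving out 1 library included. Counts stayed within 1.5 times except as follows. For genes higher in wit mutants limma-voom with sample quality weights gave 989, and a filter of more than 1 CPM in 4 libraries gave 108 genes changed 2-fold or more; the cause was not tested for the former, and fewer genes were tested in the latter (8554). Leaving out 1 library gave 304 to 1060 genes higher and 524 to 1124 genes lower in wit mutants, 146 to 217 genes changed by 2-fold or more, 8 to 12 gene lists past the test, and odds ratios for the chromosome 3 share of changed genes of 1.07 to 1.23, past the test without control replicate 2 or control replicate 4; the cause was not tested. With the replicate block 301 genes were higher and 553 lower, but replicate numbers do not pair the libraries: deviations of libraries with the same number correlated at -0.05, 0.04, -0.09 and -0.31, and 1 of 8 libraries matched its own number best. With an estimated correlation, fixed with the design, 0 lists passed. Chosen after the data were seen, genes not placed on chromosome 3, those outside the 6 arms included, held 296 higher and 459 genes lower in wit mutants, fewer by construction, and 9 lists passed there. Of 147 named genes 125 were called, and 88 of these kept their call throughout, while 37 lost it in at least 1 alternative; of 2195 gene and alternative combinations 1964 were unchanged, 215 lost a call, 16 gained one and 0 reversed. The tests for the activation and silencer elements, with their alternatives, were not run, because a genome sequence was not used here. In simulation 81.6% of 1.5-fold changes were called at this depth, so smaller ones can be missed.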

Other observations

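The groups and tests here were chosen after the values were seen, and genes outside the naming rule are named for that reason. Of 8 measured genes for octopamine and tyramine, 5 fell, 0 rose and 3 did not pass the test. The synthesis genes Tdc2 and Tbh went from 15.5 ± 1.02 to 10.3 ± 1.97 CPM and from 82.5 ± 3.31 to 45.8 ± 11.9 CPM, and the receptor gene Oct-TyrR from 41.6 ± 2.60 to 27.2 ± 0.611 CPM (edgeR adjusted p = 0.00771, 0.0173 and 8.85e-06), beside Vmat and Octbeta1R; Tbh lost its call without control replicate 3 (0.0526). Of 6 genes for heterodimeric amino acid transporters 4 fell: CG1607 from 264 to 133 CPM, and CD98hc, sbm and JhI-21 by log2 fold changes of -0.39, -0.40 and -0.30.

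Of 8 measured basement membrane genes 3 fell and 2 rose. The collagen IV genes vkg and Col4a1 and the nidogen gene Ndg (-1.01, adjusted p = 7.81e-05) fell, while the laminin genes LanA, from 177 ± 13.4 to 279 ± 24.6 CPM, and LanB2, from 52.4 ± 1.32 to 71.5 ± 8.56 CPM, rose (adjusted p = 0.000152 and 0.00241). The other 3 of the 8 measured did not pass the test, and Col4a1 lost its call without any 1 control replicate or mutant replicate 2 (adjusted p up to 0.0865).

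One hypothesis is that BMP signalling from peripheral targets may keep peptide genes on in neurons with axons outside the nerve cord. Of 9 such genes, FMRFa, CCAP, Burs, Pburs, Ilp7, Proc, Pdf, Capa and Lk, 8 were lower, and Lk had -0.16 (adjusted p = 0.234). Burs (-0.36) lost its call without any 1 control replicate or mutant replicate 2 or 4 (adjusted p 0.0899 to 0.118). Proc and Pdf fell from 538 to 217 CPM and from 71.8 to 34.1 CPM. Of the other 26 peptide genes 6 were lower, among them Orcokinin (-1.15) and Crz (-0.58), and 3 were higher, namely Nplp1 (0.35), Ptth (1.04) and CCHa1 (0.49). Whether some of these 26, Ptth among them, also come from neurons with axons outside the nerve cord was not checked. The medians differed by -1.10 (permutation p = 2.0e-05, 100000 permutations over genes, which are not independent). Because the group was assembled with the values in view, this p overstates the evidence and the hypothesis is left open. In the same way the log2 ratio of VGlut to ChAT, glutamatergic against cholinergic, was lower by -0.35 in mutants (3.0 ± 0.068 in controls, 2.65 ± 0.179 in mutants, n = 4 each, two-sided exact permutation p = 0.0286, the smallest possible), a ratio chosen after both values were known.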
